A study of Homo sapiens with 6 samples.

How the data were processed

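OE33, an established human oesophageal adenocarcinoma cell line, was profiled by RNA sequencing in 6 libraries: 3 from untreated cultures and 3 from cultures given 15 µM APX2009 for 24 h. APX2009 is a small-molecule inhibitor of the redox activity of APE1, a protein that also acts in base excision repair and whose gene is APEX1. Groups and replicate numbers were taken from the sample titles. The series design describes the replicates of each group as independent biological ones, and per the labels' protocols polyadenylated RNA was enriched with oligo(dT) beads and fragmented. The control was untreated cells, and no vehicle is named. No inactive analogue and no knockdown of APE1 is among the samples used here.

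The deposited table holds raw whole-number counts per Ensembl gene, with no normalization by the authors, for 58051 genes and 92 synthetic ERCC spike-in transcripts. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2 on GRCh38. Their order, the annotation release, the strand setting and any filter are not given in the sources used here. Without a known strand setting, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain. Among the genes named here this concerns AKR1C1, AKR1C2 and AKR1C3, HSPA1A and HSPA1B, FTH1 and its pseudogene FTH1P10, metallothioneins, histones, and ribosomal proteins with their pseudogenes. Symbols, coordinates, gene types, GC content and exon length came from GENCODE 29 (GRCh38), which matched 57447 of the 58051 IDs; unmatched IDs held 0.0348% of the gene counts.

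ERCC counts were kept out of library sizes and tests. Genes were filtered with filterByExpr at its defaults, libraries were scaled by TMM, and treatment was tested per gene with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, on treatment alone. A gene is said to have changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 changes were derived from the F statistic. Levels are CPM (counts scaled by the TMM-adjusted library size), given as mean ± SD over 3 libraries per group.

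The test, the filter, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. There were 41 lists of pathways, transcription factor targets and cell type markers, written from general knowledge. Each list with 5 or more tested members was compared with the other genes by camera of limma 3.58.1, two-sided, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 38 lists. Beside it stand the members that changed among all genes tested and those that changed when adjusted over the list alone. The text names APEX1; the 10 largest rises and 10 largest falls among changed genes with a mean log2 CPM of at least 3 and the same direction in all 9 treated-untreated pairs; up to 4 tested members of each list with the smallest p; and the 5 smallest p in each direction. Fibroblast, leukocyte and endothelial markers reaching a mean log2 CPM of 3 are also named. Some genes that this rule takes are not reported here. Any other gene named was chosen after its values were seen.

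The alternatives fixed beforehand were RLE size factors, total counts, upper-quartile factors, no filter, a filter of 1 CPM in 3 samples, leaving out each library, the replicate number as a block, leaving out mitochondrial genes with the 20 most counted genes, DESeq2 1.42.0, limma voom, an adjusted p under 0.01, a test against a 1.5-fold change, camera with an estimated correlation, camera on ranks, and fry. Scaling by the ERCC total and an offset for GC content and exon length were added after seeing the data, as were 3 gene lists and 4 lists of tissue genes. Wilson 95% intervals were computed for shares of counts in single libraries; they cover counting error only.

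The per-gene step was tested on simulated counts for the 14773 tested genes of this comparison. With edgeR, 73.1% of 67 genes simulated at 1.5-fold were recovered, 86.6% of 67 at 2-fold and 100.0% of 66 at 4-fold, and 16 unchanged genes were called, which was 8.47% of the calls. Only these 67, 67 and 66 of the 14773 genes were changed, against 34.7% called in the data. The Benjamini-Hochberg threshold depends on that share, so the recovery and the share of false calls are not those of this comparison. In simulated lists, camera recovered 10 of 10 shifted lists and called none of the others among 38. Genes were simulated as independent of each other, so this cannot show how often camera wrongly calls lists whose members vary together. Figures were drawn with matplotlib 3.10.9.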

Results

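Gene counts were measured by RNA sequencing in 3 libraries of untreated OE33 cells and 3 libraries of OE33 cells exposed to 15 µM APX2009 for 24 h. The libraries held 22568429, 25214798 and 22729641 counts in the untreated group and 26194203, 22657178 and 21315132 in the APX2009 group. At least 1 count was seen for 22207, 22322 and 22304 genes in untreated cells and for 25015, 22446 and 21845 in treated cells. Correlations of log2 CPM across genes, which are not independent replicates, ran from 0.9927 to 0.9946 between untreated libraries and from 0.9850 to 0.9934 between treated libraries. No pair of libraries within a group agreed within sampling noise, with a chi-square per degree of freedom of 3.06 to 30.00. The first principal component held 60.8% of the variance and separated the groups, and the biological coefficient of variation was 10.3%.

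The comparison shows how transcripts of these cells differ after exposure to the compound; it cannot show which of them depend on the redox activity of APE1. Treated cells had higher transcripts of NRF2 target genes, of chaperones of the endoplasmic reticulum and of aryl hydrocarbon receptor targets, with AKR1C1 72.6-fold and HMOX1 52.1-fold higher. Most tested mitosis, DNA replication and interferon-response genes were lower (40 of 40, 32 of 43 and 26 of 31), although camera did not call these lists with an estimated correlation (adjusted p = 0.181, 0.289 and 0.215), and TXNIP was 11.1-fold lower. The mRNA of APEX1 itself (ENSG00000100823, chromosome 14, 20455191 to 20457772) did not pass the test. Its level was 180.5 ± 3.48 CPM in untreated and 173.0 ± 6.70 CPM in treated cells (SD, n = 3), a log2 change of -0.06 ± 0.06 (SE; edgeR adjusted p = 0.469). An inhibitor of the protein need not change this mRNA, so it does not check the labels.

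Of 14773 genes tested, 5119 changed (34.7%), with 2543 higher and 2576 lower in treated cells (edgeR). The change was at least 2-fold for 434 of the higher and 263 of the lower genes. In 7304 genes (49.4%) the 3 treated and 3 untreated values did not overlap, where chance gives 10%, and 5059 of these were among the changed genes. When libraries were scaled by the ERCC spike-in total instead, 129 genes were higher and 7 lower, and 26 of the 155 named genes that had changed still passed. Calls were lost while changes stayed about as large: none of the named genes turned direction, the median absolute log2 change of the 155 was 0.91 with this scaling and 0.92 with TMM, and the median log2 change of all tested genes was 0.08 and 0.02. Those 26 included AKR1C1, HMOX1, GCLM, MANF, CALR, AGR2, CYP1A1, TXNIP, KRT13, PLAT and HSPG2.

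**Figure D1:**
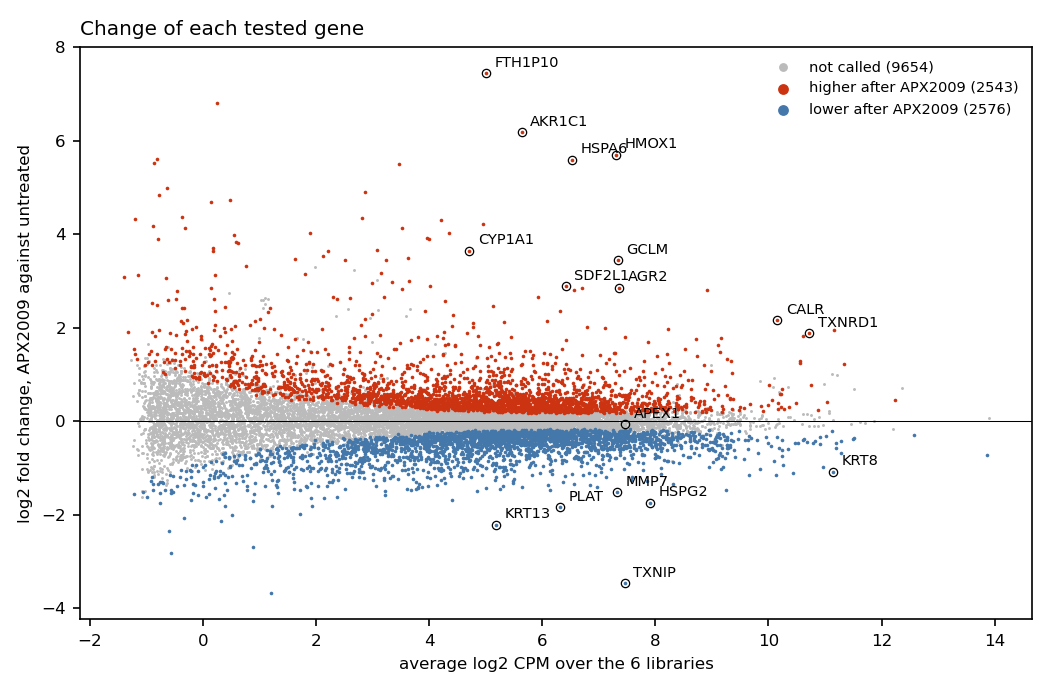
Log2 fold change of APX2009 over untreated cells against mean log2 CPM for the 14773 tested genes, with 2543 higher and 2576 lower genes coloured and 9654 others in grey. AKR1C1, HMOX1 and HSPA6 stand highest among the named genes apart from the pseudogene FTH1P10, and TXNIP stands lowest among them.

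The 10 largest rises were in genes of several kinds, among them 3 aldo-keto reductase genes and 3 pseudogenes. AKR1C1, an aldo-keto reductase (ENSG00000187134, chromosome 10, 4963253 to 4983283), went from 1.33 ± 0.332 to 98.2 ± 10.9 CPM (SD, n = 3), a log2 change of 6.18 ± 0.15 (SE; edgeR adjusted p = 4.17e-09). HMOX1, which codes for haem oxygenase (ENSG00000100292, chromosome 22, 35380361 to 35394214), went from 5.93 ± 0.233 to 309.3 ± 127.0 CPM, a log2 change of 5.70 ± 0.28 (edgeR adjusted p = 5.65e-07). HSPA6, a stress-inducible HSP70 chaperone, rose 48.4-fold with a wide spread in treated cells (181.4 ± 112.4 CPM); its log2 change of 5.60 was 4.96 without APX2009 replicate 3. AKR1C3 rose 18.7-fold, KIAA0319 17.5-fold, the transcribed pseudogene NMRAL2P 16.3-fold, AKR1C2 15.0-fold and the fatty acid hydroxylase CYP4F3 15.0-fold. The rule for the largest rises also took the processed pseudogenes FTH1P10 and RPLP0P9, whose values rest on APX2009 replicate 1. Without that library their log2 changes of 7.45 and 5.50 became 1.58 and 0.72, and RPLP0P9 no longer passed (edgeR adjusted p = 0.168). Neither passed when any untreated library was left out (edgeR adjusted p from 0.0675 to 0.0781), nor with limma voom (adjusted p = 0.398 and 0.337).

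TXNIP, which codes for a protein that binds thioredoxin and restrains glucose uptake (ENSG00000265972, chromosome 1, 145992435 to 145996600), fell most. It went from 321.5 ± 17.2 to 28.9 ± 1.68 CPM (SD, n = 3), a log2 change of -3.47 ± 0.08 (SE; edgeR adjusted p = 4.17e-09). The other large falls were in genes of several kinds. KRT13, a keratin of squamous epithelium, was 4.64-fold lower, and the keratin KRT81 3.23-fold lower. The tissue plasminogen activator gene PLAT was 3.56-fold lower, the matrix metalloproteinase gene MMP7 2.87-fold lower and the basement membrane proteoglycan gene HSPG2 3.34-fold lower. FRAS1 and the hemidesmosomal collagen gene COL17A1 were 2.83-fold and 2.78-fold lower, the lipolysis inhibitor gene G0S2 3.01-fold lower and the mitotic kinesin gene KIF20A 2.84-fold lower. MMP7, KRT13, COL17A1 and TPX2 joined TXNIP as the 5 falls with the smallest p, against MANF, AKR1C1, GCLM, SDF2L1 and CRELD2 among the rises.

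**Figure D2:**
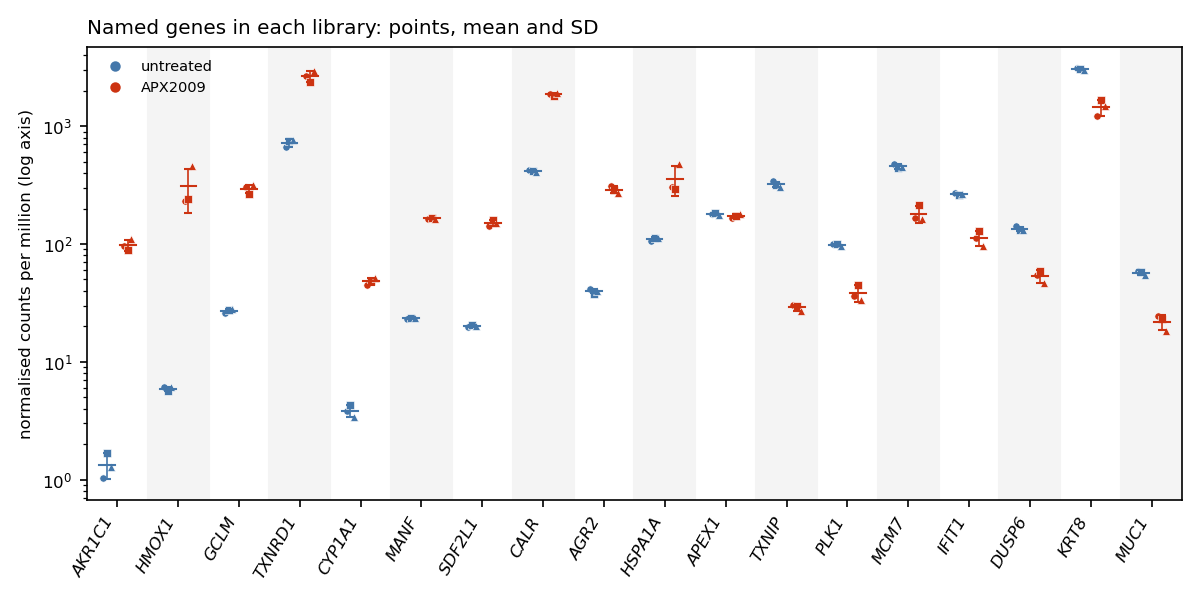
CPM on a log axis for 18 genes in each of the 3 untreated and 3 APX2009 libraries, with points for libraries and bars for the mean ± SD. Every treated library lies above every untreated one for AKR1C1, HMOX1, GCLM and MANF, and below for TXNIP, PLK1 and MCM7, while the groups of APEX1 lie close together (180.5 and 173.0 CPM).

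All 34 tested NRF2 targets, the genes of the antioxidant and electrophile response, rose, and all 34 did so adjusted over the list alone, with a median 3.15-fold rise (camera adjusted p = 1.02e-112). This call held with an estimated correlation (adjusted p = 0.0260). Besides AKR1C1 and AKR1C3, the members with the smallest p were the glutamate-cysteine ligase genes GCLM (ENSG00000023909, chromosome 1, 93885205 to 93909456), which rose 10.9-fold from 27.1 ± 1.03 to 295.9 ± 24.3 CPM (SD, n = 3), and GCLC, which rose 6.96-fold. The list of thiol and antioxidant enzymes split: 13 of 28 rose and 9 fell, against 13 and 11 adjusted over the list alone. Of the 28, 10 also stand in other lists. TXN, TXNRD1, PRDX1, GPX2, GSR, GCLC, GCLM and SRXN1 are NRF2 targets, so their rises are counted in both lists. TXNRD1, thioredoxin reductase, rose 3.69-fold to 2660 CPM beside GCLM and GCLC, while TXNIP fell. Its median log2 change was 0.01 and its mean 0.36, and camera placed it above other genes (adjusted p = 1.48e-04; adjusted p = 0.289 with an estimated correlation and 0.484 on ranks).

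Of 9 tested aryl hydrocarbon receptor targets, genes of the response to planar xenobiotics, 8 rose, also adjusted over the list alone, with a median 2.90-fold rise (camera adjusted p = 1.28e-19; adjusted p = 0.0260 with an estimated correlation). CYP1A1 rose 12.5-fold, CYP1B1 7.82-fold, ALDH3A1 3.11-fold and NQO1 2.90-fold. NQO1, whose change is the median of this list, is also in the list of NRF2 targets. In the list of iron handling and ferroptosis genes 14 of 21 rose and 3 fell, and the same numbers passed adjusted over the list alone (camera adjusted p = 3.75e-07; adjusted p = 0.181 with an estimated correlation). By p, HMOX1 led it, followed by the transferrin receptor gene TFRC (2.03-fold), the ferritin heavy chain gene FTH1 (2.34-fold) and the cystine transporter gene SLC7A11 (3.41-fold). NRF2 targets and iron genes overlap, since HMOX1, FTH1, FTL and SLC7A11 stand in both lists.

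Genes of the unfolded protein response of the endoplasmic reticulum rose as a block. All 20 tested members rose, also adjusted over the list alone, with a median 2.93-fold rise (camera adjusted p = 2.75e-99), and the call held with an estimated correlation (adjusted p = 7.51e-04). MANF, a secreted stress protein of this compartment (ENSG00000145050, chromosome 3, 51385047 to 51389397), rose 7.03-fold from 23.4 ± 0.449 to 164.8 ± 1.96 CPM (SD, n = 3). SDF2L1 rose 7.44-fold, CRELD2 7.21-fold and the chaperone gene CALR 4.49-fold, to 1868 CPM.

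The targets of ATF4 and the integrated stress response, another arm of the stress response, lay below other genes. Of 33 tested, 6 rose and 16 fell, against 6 and 18 adjusted over the list alone. The median log2 change was -0.28 and the mean -0.10 (camera adjusted p = 0.0403, or 0.779 with an estimated correlation, and fry adjusted p = 0.0871). As log2 differences from the untreated mean, list means were -0.206, -0.114 and -0.0069 in APX2009 replicates 1, 2 and 3. Untreated libraries ran from -0.0223 to 0.0263, so replicate 3 lay within their range. Among its examples DDIT3 and SLC7A11 rose 2.11-fold and 3.41-fold, while PCK2 and DDIT4 were 2.29-fold and 2.04-fold lower. Camera no longer called this list without APX2009 replicate 1 (adjusted p = 0.118), APX2009 replicate 2 (adjusted p = 0.126) or untreated replicate 2 (adjusted p = 0.0566), nor with ERCC scaling (adjusted p = 0.156) or an offset for GC content and length (adjusted p = 0.0526).

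The lists of the heat shock response, the proteasome and the lysosome also lay above other genes, each with members that did not pass. In the heat shock response list 15 of 22 rose, 17 adjusted over the list alone, with a median 1.35-fold rise (camera adjusted p = 1.40e-08; adjusted p = 0.327 with an estimated correlation). DNAJB4 rose 4.04-fold, HSPA1A 3.25-fold, HSPB8 3.10-fold and HSPA1B 2.72-fold. Of 31 proteasome subunits 16 rose and 2 fell, unchanged adjusted over the list alone, with a median 1.17-fold rise (camera adjusted p = 0.00339; adjusted p = 0.449 with an estimated correlation and 0.112 with ERCC scaling). PSMA3, PSMC5, PSMD12 and PSMC1 rose by log2 changes of 0.62, 0.50, 0.50 and 0.52. Of 30 lysosome and autophagy genes 13 rose and 1 fell, again also adjusted over the list alone (camera adjusted p = 3.33e-06; adjusted p = 0.342 with an estimated correlation). The lysosomal hydrolase genes GLA and CTSL rose 3.53-fold and 2.05-fold, and the autophagy genes GABARAPL1 and SQSTM1 2.76-fold and 2.45-fold.

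**Figure D3:**
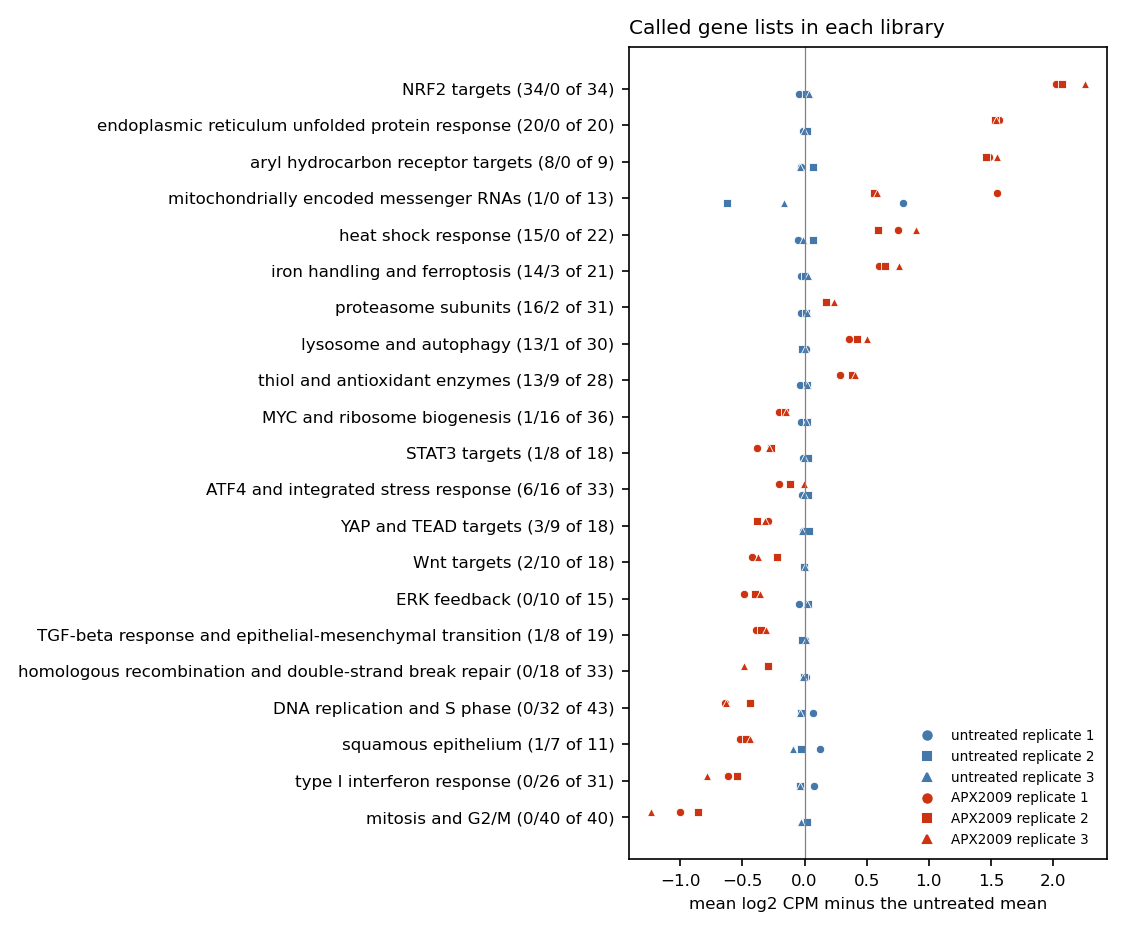
Mean log2 CPM of the members of each of the 21 lists that camera called, per library, as the difference from the untreated mean, with the number of higher and lower members. Treated libraries lie above untreated ones for NRF2 targets and the unfolded protein response and below for mitosis and interferon-response genes.

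Genes of cell division fell. All 40 tested mitosis and G2/M genes fell, also adjusted over the list alone, with a median 2.05-fold decrease (camera adjusted p = 9.67e-38; adjusted p = 0.181 with an estimated correlation). TPX2 and PLK1 were each 2.57-fold lower, the cytokinesis gene ANLN 2.19-fold and the topoisomerase gene TOP2A 2.16-fold lower. Of 43 DNA replication and S phase genes 32 fell, 34 adjusted over the list alone, with a median 1.43-fold decrease (camera adjusted p = 1.22e-12; adjusted p = 0.289 with an estimated correlation). MCM7, a subunit of the replicative helicase, went from 456.7 ± 19.1 to 180.4 ± 28.7 CPM (SD, n = 3), and RRM2, TK1 and UHRF1 were 2.49-fold, 2.40-fold and 2.07-fold lower. Of 33 genes of homologous recombination and double-strand break repair 18 fell, against 19 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.33e-04; adjusted p = 0.342 with an estimated correlation). FANCA, BARD1, RBBP8 and FANCI had log2 changes of -0.77, -0.77, -0.59 and -0.56.

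Base excision repair genes, where APE1 itself acts, showed no common shift. Of 22 tested, 3 rose and 6 fell, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.753), with a median log2 change of 0.03, a mean of -0.05 and a direction of test below other genes. NEIL2 rose by 0.48 on the log2 scale, while UNG, XRCC1 and FEN1 had log2 changes of -0.53, -0.50 and -0.39. Of 36 MYC and ribosome biogenesis genes 16 fell and 1 rose, the same adjusted over the list alone, with a median log2 change of -0.16 (camera adjusted p = 0.00724; adjusted p = 0.342 with an estimated correlation). WDR74, POLR1A, NOP2 and ODC1 had log2 changes of -0.84, -0.71, -0.46 and -0.46. Of 11 replication-dependent histone genes, whose mRNAs mostly lack poly(A) tails, 5 rose and 1 fell, against 5 and 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.541). H4C8, H2BC4, H1-2 and H2BC5 rose by log2 changes of 1.09, 0.75, 0.59 and 0.55.

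The type I interferon response fell. Of 31 tested members 26 fell, 28 adjusted over the list alone, with a median 1.55-fold decrease (camera adjusted p = 1.46e-20; adjusted p = 0.215 with an estimated correlation). OASL and IFIT1 were 2.41-fold and 2.38-fold lower, and the RNA sensor gene RIGI and ISG15 each 2.06-fold lower. Of 18 STAT3 targets 8 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 2.71e-04; adjusted p = 0.325 with an estimated correlation). MUC1, BIRC5, JUNB and CCND1 had log2 changes of -1.38, -1.01, -0.68 and -0.60. Of the 18 STAT3 targets, 9 also stand in other lists, these examples among them. BIRC5 is also in the mitosis and apoptosis lists, and CCND1 in the ERK feedback and Wnt lists. The falls of these lists are therefore not separate evidence where they share genes. NF-kappaB targets did not shift as a list: 4 of 20 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.546), with a median log2 change of -0.11, a mean of 0.05 and a direction of test below other genes. The chemokine genes CXCL8 and CXCL2 rose 2.73-fold and 1.93-fold, while ICAM1 and TNFAIP3 were 1.64-fold and 1.48-fold lower. AP-1 and immediate early genes were not called either, with 5 of 24 higher and 3 lower, 6 and 3 adjusted over the list alone (camera adjusted p = 0.295), and 10 higher and 4 lower without APX2009 replicate 1 (camera adjusted p = 0.179). JUN and ATF3 rose 3.53-fold and 2.64-fold, while JUNB and IER2 were 1.60-fold and 1.46-fold lower.

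ERK feedback genes, which growth factor signalling induces, fell. Of 15 tested, 10 fell, 11 adjusted over the list alone, with a median 1.27-fold decrease (camera adjusted p = 4.97e-06; adjusted p = 0.181 with an estimated correlation). DUSP6, an ERK phosphatase, was 2.52-fold lower, SPRY1 1.84-fold, EMP1 1.56-fold and CCND1 1.51-fold lower. Receptor tyrosine kinases and ligands were not called as a list (camera adjusted p = 0.308), with 2 of 19 higher and 6 lower, 3 and 7 adjusted over the list alone. The fry test, which sets a list against no change and not against other genes, called it (adjusted p = 0.00268). FGFR3, EPHA2 and ERBB2 were 2.03-fold, 1.71-fold and 1.39-fold lower, and the ligand gene AREG rose 1.42-fold.

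The YAP, TGF-beta and Wnt target lists lay below other genes as well. Of 18 YAP and TEAD targets 9 fell and 3 rose, 10 and 3 adjusted over the list alone (camera adjusted p = 1.92e-04; adjusted p = 0.181 with an estimated correlation), with log2 changes of -1.18 for AXL, -0.80 for AJUBA, -0.76 for NT5E and -0.61 for F3. Of 19 genes of the TGF-beta response and epithelial-mesenchymal transition 8 fell and 1 rose, 9 and 1 adjusted over the list alone (camera adjusted p = 2.94e-04; adjusted p = 0.199 with an estimated correlation). TGM2, PMEPA1 and ID1 were 2.78-fold, 1.83-fold and 1.83-fold lower. Of 18 Wnt targets 10 fell and 2 rose, 11 and 2 adjusted over the list alone (camera adjusted p = 0.00286; adjusted p = 0.342 with an estimated correlation). SOX9, RNF43 and CCND1 had log2 changes of -0.92, -0.75 and -0.60, and EPHB3 rose by 0.81.

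Metabolic lists held changed genes in both directions and were not called. Of 24 sterol biosynthesis genes 10 rose and 7 fell, 10 and 8 adjusted over the list alone (camera adjusted p = 0.312). INSIG1, HMGCS1 and MVD rose by log2 changes of 1.01, 0.81 and 0.67. Of 14 fatty acid synthesis genes 4 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.782), with a median log2 change of -0.12, a mean of 0.02 and a test direction above other genes that turned with ERCC scaling. ME1, ELOVL6 and FADS1 rose by log2 changes of 1.42, 0.48 and 0.47, and ACSS2 fell by 0.50. Of 18 glycolysis genes 3 rose and 4 fell, 3 and 5 adjusted over the list alone, with a median log2 change of -0.04 (camera adjusted p = 0.392), and without APX2009 replicate 1 5 rose and 5 fell, with a median of 0.05 (camera adjusted p = 0.817). PFKL, PKM and HK2 were 1.64-fold, 1.51-fold and 1.42-fold lower, and ENO2 rose by 0.59 on the log2 scale. Of 41 nuclear-encoded oxidative phosphorylation genes 5 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.546), with log2 changes of 0.62 for NDUFB8, -0.51 for NDUFS7, -0.49 for NDUFV1 and -0.37 for NDUFB10.

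Hypoxia and HIF1 targets were not called (camera adjusted p = 0.984): 4 of 24 rose and 1 fell, 3 and 1 adjusted over the list alone. CA12, ADM and P4HA2 rose by log2 changes of 0.58, 0.43 and 0.38, and HK2 fell by 0.51. The list's test direction, above other genes, turned with total-count scaling, ERCC scaling and several left-out libraries. CA12 no longer passed without untreated replicate 2 or 3 (edgeR adjusted p = 0.0546 and 0.0599), nor ADM without untreated replicate 2 or 3 or APX2009 replicate 3 (edgeR adjusted p = 0.0798, 0.0872 and 0.0746). Of 5 tested genes of the metallothionein and zinc export list 2 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.324). MT1E and MT1X had log2 changes of -0.48 and -0.43, and the values of MT2A and MT1F were -0.33 and -0.09 with no call. MT1X no longer passed when any library but APX2009 replicate 1 was left out (edgeR adjusted p from 0.0544 to 0.122), and MT2A passed without APX2009 replicate 1 (edgeR adjusted p = 1.84e-04).

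Lists of cell death and RNA turnover were not called. Of 27 p53 targets 8 rose and 8 fell, 9 and 8 adjusted over the list alone (camera adjusted p = 0.771). GDF15 and the apoptosis gene BAX rose 1.72-fold and 1.35-fold, while DDB2 and FDXR were 1.71-fold and 1.62-fold lower. Of 28 apoptosis regulators 5 rose and 7 fell, 5 and 8 adjusted over the list alone (camera adjusted p = 0.771), with a median log2 change of 0.05, a mean of -0.03 and a test direction below other genes. BIRC5 and BIK were 2.01-fold and 1.58-fold lower, and BMF and BAX rose 1.59-fold and 1.35-fold. Of 42 genes of mRNA decay and AU-rich element binding, relevant to the question of transcript stability, 4 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.868). Its median log2 change was 0.03 and its mean 0.01, with a test direction below other genes that turned without untreated replicate 2 (median 0.07). TIAL1 rose by 0.37 on the log2 scale, and ELAVL1, EXOSC10 and EDC4 had log2 changes of -0.36, -0.32 and -0.30. Steady-state counts do not measure transcript stability.

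Mitochondrially encoded mRNAs had their highest share in APX2009 replicate 1, a library that stood apart in its composition. Their list was called higher (camera adjusted p = 0.0313; adjusted p = 0.779 with an estimated correlation), with a median log2 change of 0.80, but not without APX2009 replicate 1 (median 0.50, adjusted p = 0.217) or untreated replicate 2 (median 0.57, adjusted p = 0.0817), nor with an offset for GC content and length (median 0.63, adjusted p = 0.0872). Of 13 genes MT-ND6 alone passed, with a log2 change of 1.21 that was 0.61 without APX2009 replicate 1 and no longer passed without that library, untreated replicate 2 or untreated replicate 3 (edgeR adjusted p = 0.0922, 0.127 and 0.125). Adjusted over the list alone 0 passed with edgeR, against 9 at an unadjusted p under 0.05, and over all genes 0 passed with DESeq2 and 3 with limma voom. MT-ND2, MT-ATP8 and MT-ND4 had log2 changes of 0.92, 1.19 and 0.98 with no call, and all of them passed without untreated replicate 1 (edgeR adjusted p = 0.00600, 0.0188 and 0.00748), MT-ATP8 also without APX2009 replicate 2 (edgeR adjusted p = 0.0389), while without APX2009 replicate 1 the log2 change of MT-ATP8 was 0.50. Mitochondrial genes took 4.12% of gene counts in APX2009 replicate 1 (Wilson 95% interval 4.12% to 4.13%) and 2.25% in both other treated libraries, against 2.62%, 0.943% and 1.33% in untreated cells. Of 40 cytosolic ribosomal protein genes 4 rose and 1 fell, and 1 passed adjusted over the list alone (camera adjusted p = 0.562); without APX2009 replicate 1, 9 rose and 4 fell (camera adjusted p = 0.817). RPL5, RPL23 and RPL7A rose by log2 changes of 0.39, 0.42 and 0.22, and RPS2 fell by 0.22. RPL23 no longer passed when any untreated library was left out (edgeR adjusted p from 0.0634 to 0.0809) and its change was 0.24 without APX2009 replicate 1. RPL7A and RPS2 each lost their call without 4 of the 6 libraries (edgeR adjusted p from 0.0512 to 0.137).

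Columnar markers changed in both directions. The columnar and intestinal list was not called (camera adjusted p = 0.771), with 5 of 22 higher and 7 lower, 5 and 8 adjusted over the list alone. AGR2, a protein disulphide isomerase of secretory epithelium, rose 7.26-fold, while MUC1 was 2.60-fold lower and the simple-epithelial keratin genes KRT8 and KRT19 2.11-fold and 1.64-fold lower. KRT19 was among the most abundant transcripts, at 18555 ± 381.9 CPM in untreated and 11303 ± 1400.4 CPM in treated cells (SD, n = 3). Of 11 tested squamous epithelium genes 7 fell and 1 rose, 7 and 2 adjusted over the list alone, with a median 1.54-fold decrease (camera adjusted p = 0.00365; adjusted p = 0.215 with an estimated correlation and 0.0540 on ranks). KRT13, IVL, SOX2 and S100A9 had log2 changes of -2.22, -0.92, -0.76 and -0.75. Of 26 epithelial junction genes 9 fell and 2 rose, 10 and 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.171), though it was called lower with no filter on low counts (adjusted p = 0.0191). Without APX2009 replicate 1, 9 fell and 5 rose. TJP3, PKP3, ESRP2 and the E-cadherin gene CDH1 had log2 changes of -0.53, -0.48, -0.39 and -0.38.

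Most markers of other cell types did not pass the expression filter, and their lists had too few tested members for camera. Of 4 tested fibroblast markers ACTA2 fell by 0.77 and TAGLN rose by 0.75 on the log2 scale, also adjusted over the list alone. TAGLN did not pass when any library other than APX2009 replicate 2 was left out (edgeR adjusted p from 0.0616 to 0.147). COL1A1 was at 10.2 ± 2.19 CPM in untreated and 11.3 ± 2.72 CPM in treated cells and COL6A3 at 0.721 ± 0.306 and 0.599 ± 0.333 CPM (SD, n = 3), with no call. Of 4 tested leukocyte markers CD68, which also marks lysosomes, rose 2.28-fold, also adjusted over the list alone. CD14, CD79A and LYZ had log2 changes of -0.18, 0.24 and -0.76 with no call. The single tested endothelial marker, ESAM, was at 7.18 ± 0.183 and 6.99 ± 1.49 CPM with no call. Some markers below the expression filter were seen mostly in APX2009 replicate 1. The fibroblast genes COL3A1, DCN and SPARC had 48, 42 and 56 counts there and at most 4 in any other library, the endothelial genes VWF and PECAM1 36 and 10 counts against at most 8 and 1, and the leukocyte gene PTPRC 6 counts against 0.

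APX2009 replicate 1 stood apart from the other treated libraries in several shares of its counts. Processed pseudogenes took 0.319% of its gene counts (Wilson 95% interval 0.317% to 0.321%), against 0.144% and 0.136% in the other treated libraries and 0.139% to 0.141% in untreated ones. ERCC spike-ins took 0.315% of its counts (Wilson 95% interval 0.313% to 0.317%), 0.752% and 0.734% in the other treated libraries and 0.553%, 0.480% and 0.564% in untreated ones. Of 52 processed pseudogenes that changed, 43 were higher; the fit without this library, counted separately, called 23 processed pseudogenes higher. Without it 5709 genes changed, and 4746 of these were among the 5119 and changed in the same direction. In that fit 1 ERK feedback gene, 1 interferon-response gene, 2 STAT3 targets and 2 MYC and ribosome biogenesis genes rose, and 2 hypoxia targets fell.

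**Figure D4:**
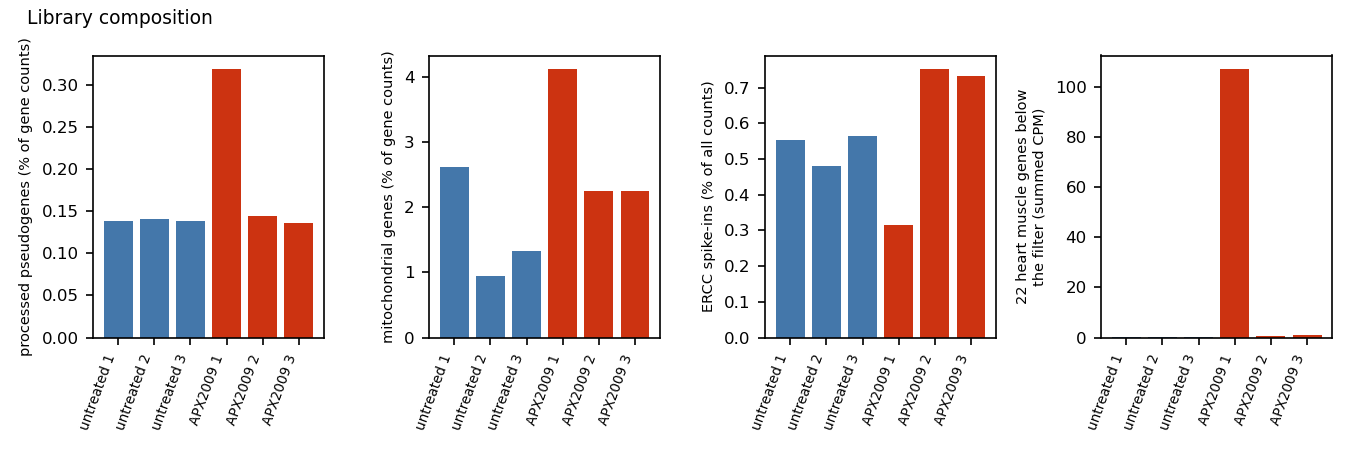
Bars, starting at 0, give for each of the 6 libraries the share of gene counts in processed pseudogenes, the share in mitochondrial genes, the ERCC share of all counts and the summed CPM of 22 heart muscle genes below the expression filter. APX2009 replicate 1 is highest in pseudogenes (0.319%), mitochondrial genes (4.12%) and heart muscle genes (107.0 CPM) and lowest in ERCC share (0.315%).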

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

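Of the tests in this part, that of ERCC proportions and that of the ERCC share were chosen after the result was seen. The tests of heart muscle genes, of mitochondrial pseudogenes and of the response slope were written down before the values they measure were seen.

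Heart muscle genes below the expression filter stood out in APX2009 replicate 1, where 22 of them summed to 107.0 CPM (2795 counts), against 0.312 CPM in the highest untreated library and 5 to 22 counts in each other library. The sarcomere genes MYH7, DES and ACTC1 had 893, 268 and 242 counts there and at most 1 in any other library; 12 of the 22 genes were listed because they had been seen to do so, and these gave 92.6 of the 107.0 CPM. The 20 heart genes listed before they were looked at summed to 72.6 CPM there (1895 counts) and to at most 23.3 CPM in any other library. This library also had the most processed pseudogene and mitochondrial counts and the fewest ERCC counts.

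These features of APX2009 replicate 1 were weighed as 1 pattern. Some fibroblast, endothelial and leukocyte transcripts were also seen mostly in this library, such as COL3A1, VWF and PTPRC with 48, 36 and 6 counts. They were not part of the tests below, so other sources of RNA in this library are not excluded. A stronger response of this culture was tested over 891 list members and is argued against there. Its difference from replicate 2 rose with the response of replicate 3 by a slope of 0.0633 (SE 0.0124, genes taken as independent). That is under the bound of 0.1 set for that explanation, but the slope was positive, so a slightly stronger response is not excluded. The heart muscle genes, processed pseudogenes and ERCC transcripts are not among these members, so the slope does not bear on them directly. Heart muscle RNA in this library may explain its heart genes. However, of these 20 heart genes 7 lay above 10 times the highest other library, between the bounds set. Of the 20, 10 passed the expression filter, and a baseline in OE33 can hide a rise in some of them. MB was at 5.15 to 8.29 CPM in the other libraries and 9.19 CPM in APX2009 replicate 1. TNNT2 and LDB3 reached at most 0.756 and 0.624 CPM in the other libraries and 6.013 and 5.515 CPM in APX2009 replicate 1. They thus rose there, but by less than 10 times. Of the 7 above that bound, TNNI3K had 1 count in APX2009 replicate 1 and 0 in every other library. Of skeletal muscle genes with any count 0 of 6 lay above 10 times the highest other library. This was judged by the ratio of CPM with no test, and of liver genes 1 of 5 did so. Whether human heart RNA would account for the pseudogenes too stays open, since the median log2 ratio of 11 mitochondrial pseudogenes to their genes was -11.68 there and -13.42 to -12.13 elsewhere, above that range by less than its width. A difference in library preparation or sequencing remains open and is in line with the ERCC transcripts, whose proportions departed from the untreated mean with an SD of log2 ratios of 0.442, against 0.181 and 0.192 in the other treated libraries (33 transcripts).

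The ERCC share of counts in APX2009 replicates 2 and 3, 0.752% and 0.734%, exceeded the highest untreated share of 0.564%, while replicate 1, at 0.315%, lay below the lowest untreated share of 0.480%. Less mRNA per unit of total RNA after treatment might raise the share, and 2 of the 3 treated libraries lay above every untreated one. The explanation cannot be told apart from differences in the spike-in amount added, which is not given in the sources used here, and replicate 1 differs in composition. With libraries scaled by the ERCC total the median log2 change of all tested genes was 0.08, against 0.02 with TMM, and 129 genes were called higher and 7 lower.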

How the results depend on the processing

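The ERCC scaling and the GC and length offset were chosen after seeing the data; all other alternatives were planned. Counts of changed genes were within 1.5 times the main counts under RLE, total-count and upper-quartile scaling, the stricter filter, the GC offset, DESeq2 (4551 genes), limma voom (5098 genes) and each left-out library (3503 to 5709 genes, of which 3464 to 4746 were among the 5119 in the same direction). With ERCC scaling 136 genes changed, 129 higher and 7 lower, all of them at least 2-fold (129 and 7). They came from 682 at an unadjusted p under 0.05, and 113 were among the 5119. The median log2 change moved from 0.02 to 0.08. The ERCC share was 0.315% in APX2009 replicate 1 against 0.752% and 0.734% in replicates 2 and 3. This scaling therefore spread the treated libraries apart within their group. Whether that spread accounts for the lost calls was not tested. Without a filter 724 genes were at least 2-fold higher, with more low-count genes tested. An adjusted p under 0.01 left 3057 genes (1470 higher, 1587 lower), and a test against a 1.5-fold change 606 (351 and 255, with 270 at least 2-fold higher), as stricter thresholds do. With an estimated correlation camera called 3 lists higher and 0 lower (4 lower at an unadjusted p under 0.05). The fry test, which sets a list against no change and not against other genes, called 8 and 12. The cause of the calls that camera lost was not tested. The unfolded protein response list had an estimated correlation of -0.018, below the preset 0.01. Its camera p still went from 1.45e-100 to 1.98e-05, so wider correlation is not the cause for that list. A call lost with an estimated correlation, for any list named above, therefore does not by itself show that its members vary together. The labels do not say that equal replicate numbers share a day. Same-numbered libraries had deviation correlations of 0.14, 0.08 and 0.01 across genes, and untreated replicate 2 correlated best with APX2009 replicate 3 (0.11). With so few libraries these correlations cannot tell whether the numbers pair the samples. The replicate block gave 5501 genes (2757 higher, 2744 lower) and 9 and 11 lists, ending the call of ATF4 targets (adjusted p = 0.0554). APEX1 passed under none of the alternatives. Among named genes and APEX1, 2630 values over all alternatives kept direction and call, 175 lost the call (129 of them with ERCC scaling), 17 gained one and 4 changed sign; for lists the numbers were 633, 32, 2 and 16. All sign changes were in uncalled results, and their cause was not tested. For hypoxia targets the test turned with list medians of 0.0772 (total counts), 0.0428 (no filter), 0.0721 (replicate block), 0.0685 (without mitochondrial and most counted genes), 0.0620 (ERCC) and 0.0255 (GC offset), and -0.0319 to 0.1438 over left-out libraries. For columnar markers it turned at -0.2498 (without mitochondrial and most counted genes) and -0.2486 (GC offset), with -0.3994 to -0.2266 over left-out libraries. For fatty acid synthesis it turned at -0.0841 (ERCC) and -0.1225 (ranks), and for mRNA decay over left-out libraries, from -0.0346 to 0.0655. COL1A1 ran from -0.0572 to 0.3408, COL6A3 from -0.7876 to 0.1632 and ESAM from -0.1676 to 0.1227 over left-out libraries. In simulated counts of this depth 73.1% of 1.5-fold changes were found. Far fewer genes were changed there than were called here, so that share does not carry over to these data. Small changes may still be missed. Without APX2009 replicate 1, 5709 genes changed.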

Other observations

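The test of basement membrane genes and that of the distance between stress lists were chosen after the result was seen; the tests of endoplasmic reticulum entry and export, antigen presentation, GC trend, left-out library and other splits were written down first. The 3 gene lists used here were added after seeing the data, and their example genes were chosen after their values were seen.

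Genes for protein entry into and export from the endoplasmic reticulum rose beside the chaperones. Of 53 tested, none of them in a list fixed earlier, 46 rose and 7 did not pass, with a median log2 change of 0.49 (camera adjusted p = 9.10e-27 over the 3 added lists; adjusted p = 0.00182 with an estimated correlation). The translocon genes SEC61G and SEC61A1 rose 2.26-fold and 1.83-fold, the cargo receptor gene TMED7 2.08-fold, the signal peptidase gene SPCS2 1.94-fold and SSR3 1.98-fold (edgeR adjusted p = 2.52e-05, 5.03e-05, 7.48e-05, 2.70e-06 and 6.60e-06). Outside these lists ERO1B rose 7.44-fold, NUCB2 6.30-fold, FICD 3.77-fold and EIF2AK3, which codes for the stress kinase PERK, 2.70-fold. Over the same treatment the amino acid synthesis genes ASNS, PSAT1 and PHGDH, all ATF4 targets, had log2 changes of -0.73, -0.58 and -0.50, while ATF4 itself rose 1.24-fold. The mean log2 CPM of the unfolded protein response list minus that of the ATF4 list was -0.55 ± 0.0058 in untreated and 1.11 ± 0.115 in treated libraries (SD, n = 3). This distance was computed because the lists had been seen to move apart, and its exact permutation p of 0.10, two-sided, is the smallest that 3 against 3 can give, so it decides nothing further.

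Class I antigen presentation genes were lower beside the interferon list. Of 19 tested, 1 of which also stands in a fixed list, 10 fell and 2 rose, with a median log2 change of -0.27 (camera adjusted p = 0.00456 over the added lists; adjusted p = 0.375 with an estimated correlation). HLA-F, HLA-C and HLA-B had log2 changes of -0.80, -0.58 and -0.48, and the peptide transporter gene TAP1 -0.58. ERAP1 and ERAP2 rose by 0.47 and 0.19, and B2M had a log2 change of -0.10 with no call. Basement membrane adhesion genes also lay lower: 18 of 24 fell and 2 rose, with a median log2 change of -0.58 (camera adjusted p = 8.08e-11; adjusted p = 0.106 with an estimated correlation). AGRN, LAMA5, ITGB4 and PLEC were 2.21-fold, 1.91-fold, 1.98-fold and 1.99-fold lower, and DST and the barely detected COL4A1 (0.015 to 0.905 CPM) rose. HSPG2, FRAS1 and COL17A1 led to this list, and 2 members stand in fixed lists, so it is not independent evidence.

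The fall of mitosis and DNA replication genes was weighed against 2 technical explanations. A trend with GC content, which reached a rank correlation of -0.31 across genes in APX2009 replicate 1, is argued against as the whole cause, since the median log2 change of the mitosis list was -1.09 with the trend removed and -1.04 with it. APX2009 replicate 1 alone is argued against too, with a median of -1.04 without it. Fewer dividing cells after treatment is a hypothesis that stays untested, as no cell count or cycle measurement was used here.

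Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 5119 genes or more with edgeR. The highest other gave 0, with 114 to 425 genes at an unadjusted p under 0.05 against 6623 for the real one. Such splits are too few for a share under 0.05. Every other split also mixed treated and untreated libraries in each group, so a treatment difference widened the spread within its groups and lowered its calls. Their counts are therefore not those of groups without a treatment difference.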
